A study of Mus musculus with 19 samples.

How the data were processed

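Whole inguinal adipose tissue of 19 wild-type C57BL/6JRj mice was profiled by 3' RNA sequencing, and each library came from 1 mouse. Per the labels' protocols, mice were kept at 29 °C after 14 days of acclimatization, and CHX207 fibrosarcoma cells (a mouse sarcoma line) were injected into the calf muscle. Tissue was taken 14 days after the injection. Per the labels, healthy mice received control AAV and PBS, and mice with tumours received control AAV, FGF21 AAV (an adeno-associated virus carrying the hormone FGF21) or efruxifermin, an engineered FGF21 protein given at 2 mg/kg in 6 injections. Treatment began 9 days before the tumour cells. The labels do not say that efruxifermin mice also had control AAV, so the efruxifermin comparisons contrast the drug with virus-treated controls.

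Per the submitters' processing notes, the authors used FastQC, cutadapt, HISAT2 and HTSeq with the GRCm39 mouse genome, without stating versions or the strand setting, on libraries of the QuantSeq 3' kit. The deposited table gives RPM, which per the labels is reads scaled to library size, for 24844 genes, 1 column per mouse. Each column sums to the same total, and in 19 of 19 libraries values of up to 1000 reads are multiples of the value of 1 read, so whole reads were recovered. Of these values, 100% lay within 0.05 of a whole number. The recovered depth was 2011067 to 3693864 reads per library. Floors and intervals printed here cover counting error only, since PCR reads without molecular identifiers are not independent molecules. No coordinates are given, since the table has none and the annotation at hand was for another genome build.

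Groups and comparisons were taken from the labels before the data were examined: tumour control against healthy, each treatment against tumour control, the treatments against each other, and each treatment against healthy. Genes with an RPM of 1 or more in at least 4 libraries were tested (17013 genes). The 4 groups were fitted together by limma 3.58.1 in R 4.3.3 on log2(RPM + 1) with the trend option. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. Fold changes are on this log2(RPM + 1) scale and understate the change of low genes. Beside each list, the number of members that pass when p is adjusted over the list alone is given. The 37 fixed lists (pathways, cell type markers, other tissues) were tested by camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation and by fry. With the estimated correlation, 2 lists were called in FGF21 AAV against healthy and 0 in the other 5 comparisons.

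Genes named in the text are those of a fixed rule. It took Fgf21, its receptor genes and 6 fat genes. It took the 8 largest rises and 8 largest falls among called genes of mean RPM 5 or more. It also took the 4 members with the smallest p of each list that was called or had 3 called members. Names outside this rule are said to be so where they appear.

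Alternatives were other pseudocounts (0.25 and 5), filters, scalings (TMM factors and edgeR 4.0.16 quasi-likelihood tests, DESeq2 1.42.0 size factors and tests on recovered reads), covariates and leaving out each library. By edgeR, 1, 8, 46, 0, 1 and 0 genes were called in tumour control against healthy, FGF21 AAV against tumour control, efruxifermin against tumour control, efruxifermin against FGF21 AAV, FGF21 AAV against healthy and efruxifermin against healthy. By DESeq2 the counts were 39, 521, 400, 19, 28 and 17 in the same order. Replicate numbers were tested as a pairing. Of 27 pairs of libraries with the same number 8 correlated above 0.1, and of 108 pairs with other numbers 24 did. The median correlations were -0.0199 and -0.00839. Of 19 libraries 7 correlated best with their own number. This leaves a weak pairing possible, but the labels state none, so the comparisons are unpaired. No pair of libraries was a duplicate.

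Lymph node RNA (B cell markers) and skeletal muscle RNA were scored in each library as the mean log2(RPM + 1) of marker lists fixed in advance. A B cell score above 3 separated libraries with lymph node RNA, a value chosen after the scores were seen. The pipeline was tested on simulated reads with real dispersions: of 66 or 67 genes changed 8-fold, 53.0% to 68.2% were recovered, 25.4% to 50.7% at 4-fold, and 0 to 5.97% at 2-fold, over the 6 comparisons. In these simulations 0 to 6 unchanged genes were called. Genes were drawn independently, so RNA of neighbouring tissues that moves many genes together was not simulated. These rates hold for independent genes only. A division of the real libraries that called 1723 genes is no measure of false calls, since it kept most libraries in their real groups. Where a gene had 0 reads in a group, folds are lower bounds against 3 reads over the group. Intervals for ratios of reads are exact 95% binomial intervals. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.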

Results

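RNA of whole inguinal adipose tissue was sequenced from the 3' end in 19 mice held at thermoneutrality: 4 healthy mice given control AAV and 3 groups of 5 mice with a CHX207 fibrosarcoma. The tumour groups received control AAV, FGF21 AAV or efruxifermin, an FGF21 analogue. The study's title places FGF21 against the metabolic dysfunction of cancer cachexia, the wasting of fat and muscle that tumours bring. The depth was 2693930 to 2844145 reads per library in healthy mice, 2106634 to 3693864 in tumour controls, 2011067 to 3209666 under FGF21 AAV and 2676014 to 3196674 under efruxifermin. Between 12537 and 17040 genes were detected per library. The mean was 16640 ± 637 in healthy mice (SD, n = 4) and 15600 ± 610 in tumour controls. It was 15340 ± 1070 under FGF21 AAV and 14190 ± 1510 under efruxifermin (SD, n = 5 each).

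The libraries differed in RNA of neighbouring tissues. B cell markers, a sign of the inguinal lymph node, were present (score above 3) in 2 of 4 healthy, 4 of 5 tumour control, 2 of 5 FGF21 AAV and 3 of 5 efruxifermin libraries. The mean B cell score was 3.64 ± 3.56 (SD, n = 4) in healthy mice, 6.20 ± 3.18 (SD, n = 5) in tumour controls, 2.75 ± 2.63 (SD, n = 5) under FGF21 AAV and 4.00 ± 2.60 (SD, n = 5) under efruxifermin. The skeletal muscle score averaged 7.66 ± 2.89 (SD, n = 4), 4.69 ± 4.00 (SD, n = 5), 2.58 ± 2.31 (SD, n = 5) and 4.49 ± 2.90 (SD, n = 5) in the same order. Tumour control 4 stood apart from the other tumour controls, with a B cell score of 0.59 and a muscle score of 11.2. Efruxifermin 3 stood apart from the other efruxifermin libraries, with the fewest genes detected (12537), a Gm42418 share of 17.3% and a muscle score of 8.29. Gm42418, named after its values were seen, overlaps ribosomal RNA and took 3.34 ± 1.06% of reads in healthy mice (SD, n = 4), 5.97 ± 2.00% in tumour controls, 9.34 ± 4.94% under FGF21 AAV and 8.34 ± 5.38% under efruxifermin (SD, n = 5 each). Mitochondrial genes took 6.91 ± 2.11% (SD, n = 4), 7.53 ± 3.90%, 10.1 ± 2.25% and 9.08 ± 1.57% (SD, n = 5 each) in the same order.

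**Figure D1:**
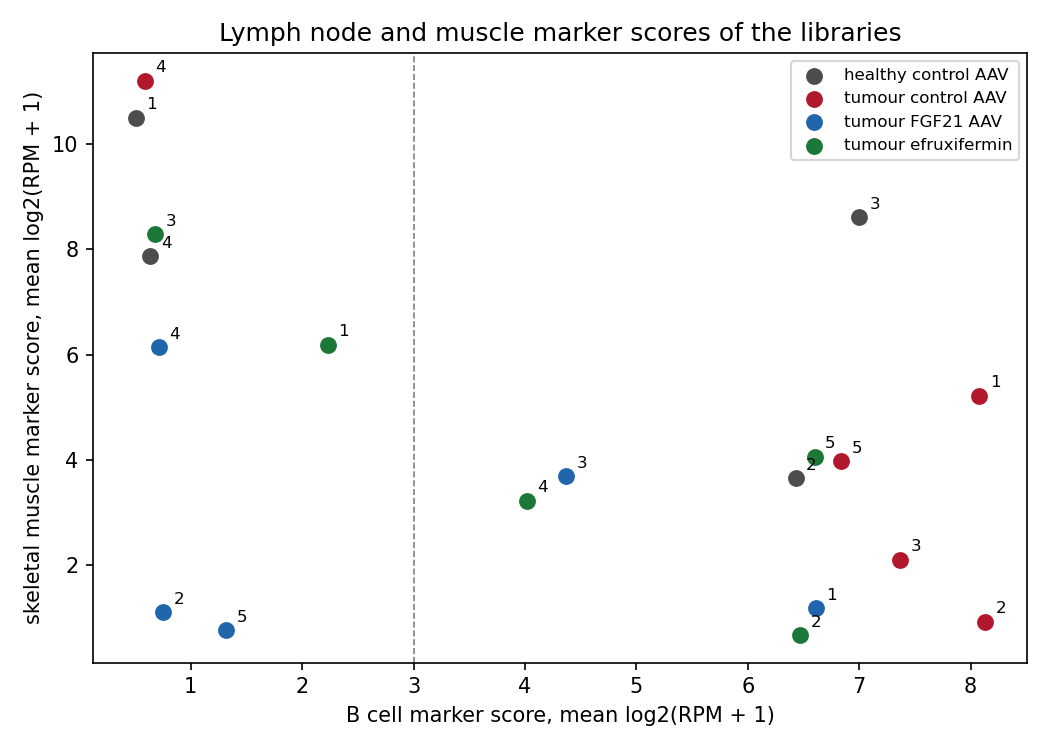
Mean log2(RPM + 1) of B cell markers (horizontal axis) against that of skeletal muscle markers (vertical axis) in the 19 libraries, coloured by group and numbered by replicate. The dashed line is the score of 3, and 4 of the 5 tumour control libraries lie to its right.

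Fgf21 had 0 reads in the healthy, FGF21 AAV and efruxifermin libraries, which allows up to 0.272, 0.228 and 0.201 RPM over each group, and 2 reads in tumour control 2. Whether transcripts of the virus would be counted as Fgf21 in these 3' libraries was not tested, so 0 reads do not exclude them. Ucp1, the uncoupling protein of thermogenic fat, had 0 RPM in healthy and tumour control libraries and 0.953 ± 2.13 (SD, n = 5) and 0.188 ± 0.419 RPM (SD, n = 5) under FGF21 AAV and efruxifermin.

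Comparing tumour controls with healthy mice asks what the tumour did to this fat depot. Extracellular matrix genes were lower in tumour-bearing mice. Among 30 tested members 2 fell over all genes and 22 when adjusted over the list alone, with a median log2 change of -1.67 (camera adjusted p = 2.34e-23, adjusted p = 0.107 with an estimated correlation). Col5a3, a fibrillar collagen chain, fell 5-fold to 27.4 ± 13.5 RPM (SD, n = 5), from 141 ± 71.9 RPM (SD, n = 4), and Npr3, the natriuretic peptide clearance receptor, fell 6.74-fold (log2 -2.75 ± 0.52 SE). The fixed list holds Npr3 beside matrix genes, so of the 2 called members only Col5a3 is a matrix gene. Acta2, smooth muscle actin, fell 3.95-fold (log2 -1.98 ± 0.30 SE), and 7 of 12 mural cell markers fell when adjusted over the list alone (median -1.19, adjusted p = 5.3e-07, adjusted p = 0.107 with an estimated correlation). Sncg, an adipocyte gene of the synuclein family, fell 7.22-fold, Gas6, a ligand of TAM receptors, 4.73-fold, Slc5a3, the myo-inositol transporter, 4.05-fold, and Dapk1, a kinase of cell death, 2.78-fold. Alb, the albumin gene, had 361 reads in healthy mice and 1 read in tumour controls, a ratio of 453 (95% interval 80.8 to 17900).

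Genes of fat storage and release were lower as groups. Of 21 lipolysis and lipid droplet genes, 0 passed over all genes in limma and 9 fell when adjusted over the list alone, with a median of -1.14 (adjusted p = 1.3e-09, adjusted p = 0.154 with an estimated correlation). Plin1, the coat protein of lipid droplets, gave -1.90 ± 0.53 (SE, adjusted p = 0.185) and Aqp7, the glycerol channel, -1.59 ± 0.42 (SE, adjusted p = 0.172). In lipid uptake 8 of 16 members fell when adjusted over the list alone (median -1.27, adjusted p = 7.14e-09, adjusted p = 0.124 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, gave -2.11 ± 0.44 (SE, adjusted p = 0.0611), and Lpl, that lipase, -1.65 ± 0.48 (SE, adjusted p = 0.217). Among 15 adipokines 9 fell when adjusted over the list alone (median -1.44, adjusted p = 1.11e-07, adjusted p = 0.154 with an estimated correlation). Lep, the leptin gene, stood at 15.4 ± 10.9 RPM (SD, n = 5) against 39.4 ± 14.4 RPM (SD, n = 4), and Adipoq, adiponectin, at 312 ± 185 RPM (SD, n = 5) against 1120 ± 717 RPM (SD, n = 4), with neither past the threshold. Branched-chain amino acid catabolism was lower (4 of 19 fell adjusted over the list alone, median -0.78, adjusted p = 1.24e-07, adjusted p = 0.154 with an estimated correlation). So was fatty acid oxidation (1 of 23 adjusted over the list alone, median -0.71, adjusted p = 4.97e-08, adjusted p = 0.154 with an estimated correlation).

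Markers of other tissues moved with these groups. B cell markers had a median of 2.55 (adjusted p = 7.14e-09, adjusted p = 0.282 with an estimated correlation). T and NK cell markers had 1.52 (adjusted p = 2.44e-05, adjusted p = 0.377 with an estimated correlation), and muscle markers -2.89 (adjusted p = 2.39e-05, adjusted p = 0.368 with an estimated correlation). Of 26 cell cycle genes 0 were called by limma, with a median of 0.89 (adjusted p = 5.59e-07, adjusted p = 0.343 with an estimated correlation). In all, 8 genes were called, 0 higher and 8 lower, with 1415 at an unadjusted p under 0.05, and 29 of 37 lists were called. The count was 1, 3, 4, 17, 64 and 42 without healthy 4, tumour control 1, 2, 3, 4 and 5. It was 13 with B cell and muscle scores as covariates, 0 in the libraries with lymph node RNA (4 against 2), 0 in those without it (1 against 2, too few to tell), 1 when only these 2 groups were fitted, 1 by edgeR and 39 by DESeq2. Interferon response genes had a median of -0.00276 and a mean of 0.137 over 24 members, with the test upward (adjusted p = 0.0374, adjusted p = 0.552 with an estimated correlation), and the median was above 0 under 3 other scalings (0.118, 0.149 and 0.202). The median over all genes of the shift in log2 fold change was up to 0.277 with quantile normalization (efruxifermin against healthy), 0.146 with median-of-ratios factors (here), 0.133 with TMM factors (FGF21 AAV against healthy) and 0.159 without the 50 most abundant genes (FGF21 AAV against healthy).

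Comparing FGF21 AAV with tumour controls asks what the hormone did in mice with a tumour. Genes of lipid handling rose. Among lipid uptake genes 5 of 16 rose over all genes and 10 when adjusted over the list alone (median 1.56, adjusted p = 7.43e-11, adjusted p = 0.125 with an estimated correlation). Lpl rose 4.18-fold to 6700 ± 1220 RPM (SD, n = 5), Fabp4, the fatty acid carrier of adipocytes, 5.41-fold, Lrp1 3.21-fold and Cavin2, a protein of caveolae, 3.09-fold. Of 21 lipolysis and lipid droplet genes 3 rose over all genes and 17 when adjusted over the list alone (median 1.5, adjusted p = 2.85e-14, adjusted p = 0.125 with an estimated correlation). Adora1, the adenosine receptor that restrains lipolysis, rose 7.28-fold, Prkar2b, a regulatory subunit of protein kinase A, 5.36-fold, and Aqp7 3.75-fold. Pck1, the enzyme of glyceroneogenesis, rose 7.71-fold (log2 2.95 ± 0.57 SE), and 10 of 15 triglyceride synthesis genes rose when adjusted over the list alone (median 1.14, adjusted p = 8.16e-08, adjusted p = 0.165 with an estimated correlation).

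Adipokines rose as well: 3 of 15 over all genes and 10 when adjusted over the list alone (median 1.5, adjusted p = 1.1e-09, adjusted p = 0.127 with an estimated correlation). Lep rose 5.72-fold to 74.4 ± 23.6 RPM (SD, n = 5), Rbp4, the retinol carrier, 5.24-fold, and Ccdc80, a secreted matrix protein, 3.57-fold. Lep passed the threshold in 16 of 33 alternatives, Rbp4 in 22 of 33 and Ccdc80 in 18 of 32. Adipoq stood at 1260 ± 684 RPM (SD, n = 5, adjusted p = 0.0807), and Pnpla2, the first triglyceride lipase, at 981 ± 453 RPM (SD, n = 5, adjusted p = 0.0636). Branched-chain amino acid catabolism (1 of 19 over all genes, 12 adjusted over the list alone, median 0.86, adjusted p = 8.29e-09, adjusted p = 0.127 with an estimated correlation) rose with Dbt, a subunit of its committed step, 2.15-fold. Fatty acid oxidation (1 of 23 over all genes, 9 adjusted over the list alone, median 0.60, adjusted p = 8.29e-09, adjusted p = 0.127 with an estimated correlation) rose with Etfb, an electron carrier, 2.25-fold. Dbt and Etfb each passed the threshold in 13 of 33 alternatives. Fgfr1, the FGF21 receptor in fat, rose 2.86-fold to 135 ± 31.5 RPM (SD, n = 5) from 48.3 ± 18.8 RPM (SD, n = 5), and its co-receptor Klb had 6.28 ± 5.29 against 2.46 ± 2.65 RPM (SD, n = 5 each, adjusted p = 0.602). The FGF and ERK target list had 1 of 17 rise over all genes and 2 adjusted over the list alone (median 0.58, adjusted p = 0.00111, adjusted p = 0.125 with an estimated correlation).

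Clock genes rose: 2 of 17 over all genes, 9 up and 1 down adjusted over the list alone (median 0.94, adjusted p = 1.94e-06, adjusted p = 0.125 with an estimated correlation), with Dbp, an output gene of the clock, 4.13-fold and Per3 3.91-fold. In the extracellular matrix list Npr3 rose 10.6-fold and Col5a3 4.03-fold, with 8 of 30 adjusted over the list alone (median 0.96, adjusted p = 2.53e-10, adjusted p = 0.193 with an estimated correlation). Of 16 tested plasma protein and liver genes, a list drawn up after the values were seen and not among the 37, 5 rose: Alb had 789 reads against 1 (ratio 830, 95% interval 149 to 32800), Ahsg 156 reads against 1 (ratio 164, 95% interval 29.0 to 6520), and Ttr, transthyretin, 295 reads against 0, at least 103-fold higher over the group. Hpx, hemopexin, rose 18.7-fold and Apoa1 13.6-fold. Hmmr, a gene of dividing cells, fell 9.75-fold. Over 32 alternatives its log2 change ran from -5.07 to -0.345, and it passed the threshold in 14 of them. Of 26 cell cycle genes 6 fell adjusted over the list alone (median -1.80, adjusted p = 1.63e-09, adjusted p = 0.246 with an estimated correlation). Ptp4a3, a phosphatase, fell 5.07-fold and Mef2c, a transcription factor of muscle and lymphoid cells, 3.89-fold.

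B cell markers had a median of -3.33 (adjusted p = 2.41e-07, adjusted p = 0.315 with an estimated correlation). T and NK cell markers had -2.99 (adjusted p = 1.09e-06, adjusted p = 0.346 with an estimated correlation) and muscle markers -2.42 (adjusted p = 0.00332, adjusted p = 0.518 with an estimated correlation). Mammary epithelial markers were higher, 11 of 17 adjusted over the list alone (median 1.25, adjusted p = 2.8e-07, adjusted p = 0.125 with an estimated correlation). Red blood cell markers were higher in 5 of 9 cases adjusted over the list alone (median 1.30, adjusted p = 9.46e-05, adjusted p = 0.179 with an estimated correlation). Mural (median 0.90, adjusted p = 0.00225, adjusted p = 0.179 with an estimated correlation) and endothelial markers (median 0.60, adjusted p = 0.000917, adjusted p = 0.207 with an estimated correlation) were higher too. In this comparison 96 genes were called, 88 higher and 8 lower, and 22 of 37 lists. The count was 8, 8, 1015 and 215 without tumour control 1, 2, 4 and 5, and 19, 9, 7 and 8 without FGF21 AAV 2, 3, 4 and 5. It was 1 with B cell and muscle scores as covariates, 1 in the libraries with lymph node RNA (2 against 4), 0 in those without (3 against 1, too few to tell), 158 without Gm42418, 8 by edgeR and 521 by DESeq2.

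**Figure D2:**
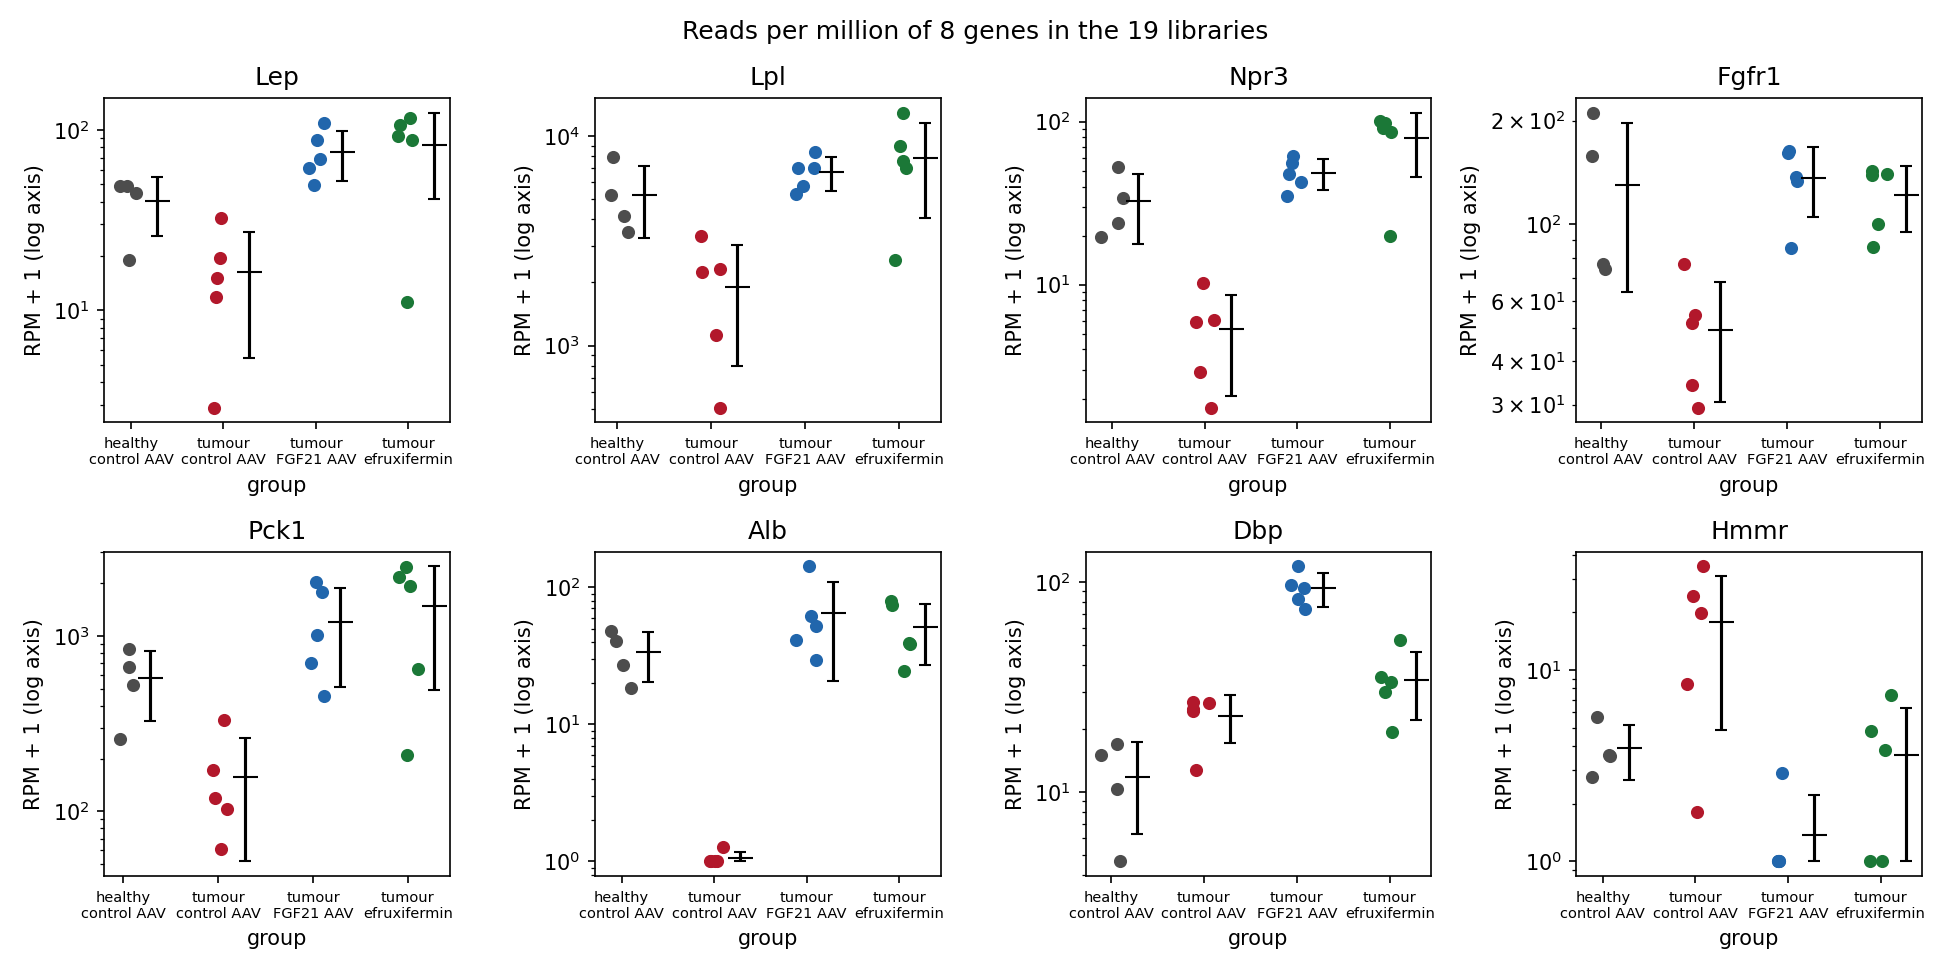
RPM + 1 on a log axis for 8 genes, 1 point per library, with the mean and SD of each group in black beside its points. All 5 FGF21 AAV libraries were above all 5 tumour controls for Lep, Lpl, Npr3, Fgfr1, Pck1, Alb and Dbp, and 4 of 5 were below all of them for Hmmr.

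Comparing efruxifermin with tumour controls asks the same of the engineered protein. Lipid uptake genes rose, 5 of 16 over all genes and 10 adjusted over the list alone (median 1.22, adjusted p = 1.32e-10, adjusted p = 0.138 with an estimated correlation). Cav1, caveolin, rose 4.99-fold, Lpl 4.37-fold, Lrp1 3.15-fold and Cavin2 2.70-fold. Of the lipolysis and lipid droplet genes 3 of 21 rose over all genes and 16 adjusted over the list alone (median 1.57, adjusted p = 3.01e-16, adjusted p = 0.138 with an estimated correlation). Prkar2b rose 5.13-fold, Aqp7 4.76-fold and Mgll, the monoglyceride lipase, 2.97-fold. Pck1 rose 8.01-fold, with 7 of 15 triglyceride synthesis genes adjusted over the list alone (median 1.30, adjusted p = 1.63e-09, adjusted p = 0.138 with an estimated correlation). Adipokines rose, 4 of 15 over all genes and 9 adjusted over the list alone (median 1.59, adjusted p = 1.47e-10, adjusted p = 0.138 with an estimated correlation). Agt, angiotensinogen, rose 7.86-fold, Rbp4 6.56-fold and Itih5 3.80-fold, while Lep stood at 81.8 ± 41.6 RPM (SD, n = 5, adjusted p = 0.0586). Over 33 alternatives Agt passed the threshold in 13, Rbp4 in 29 and Itih5 in 22.

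Genes of the extracellular matrix list, which includes the receptor gene Npr3, rose in 4 of 30 cases over all genes and 9 adjusted over the list alone (median 1.16, adjusted p = 3.01e-16, adjusted p = 0.138 with an estimated correlation). Npr3 rose 15.3-fold, Col5a3 7.87-fold, Col4a2, a basement membrane collagen, 3.20-fold and Sparc 3.05-fold. Fgfr1 rose 2.56-fold to 121 ± 26.4 RPM (SD, n = 5). Endothelial markers rose in 7 of 15 cases adjusted over the list alone and in 0 over all genes in limma (median 0.64, adjusted p = 9.72e-06, adjusted p = 0.138 with an estimated correlation), and Cd163, a marker of resident macrophages, rose 6.21-fold. Fgfr1 and Cd163 each passed the threshold in 16 of 33 alternatives. Of the acute phase list Orm1 rose 12.1-fold and Hp, haptoglobin, 9.25-fold. In that list 2 of 27 rose over all genes, and 3 rose and 1 fell adjusted over the list alone (median 0.41, adjusted p = 0.00452, adjusted p = 0.323 with an estimated correlation). Alb had 749 reads against 1 (ratio 696, 95% interval 125 to 27500), and Hpx rose 13.8-fold. Mef2c fell 2.80-fold, Sema4d, a semaphorin of lymphocytes, 8.44-fold and L1cam, an adhesion molecule, 8.08-fold.

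B cell markers had a median of -2.13 (adjusted p = 0.00233, adjusted p = 0.52 with an estimated correlation). T and NK cell markers had -2.95 (adjusted p = 8.04e-06, adjusted p = 0.395 with an estimated correlation) and muscle markers -0.06 (adjusted p = 0.915), which quantile normalization turned to 0.257. Mammary epithelial (median 0.71, adjusted p = 0.00244, adjusted p = 0.295 with an estimated correlation), red blood cell (median 0.99, adjusted p = 0.0256, adjusted p = 0.445 with an estimated correlation) and mural markers (median 0.48, adjusted p = 0.00183, adjusted p = 0.181 with an estimated correlation) were higher. In all, 130 genes were called, 115 higher and 15 lower, and 22 of 37 lists. The count was 21, 21 and 599 without tumour control 1, 2 and 4, and 4, 74, 377 and 5 without efruxifermin 1, 2, 3 and 4. It was 41 with B cell and muscle scores as covariates, 298 in the libraries with lymph node RNA (3 against 4), 0 in those without (2 against 1, too few to tell), 1 when only these 2 groups were fitted, 46 by edgeR and 400 by DESeq2.

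**Figure D3:**
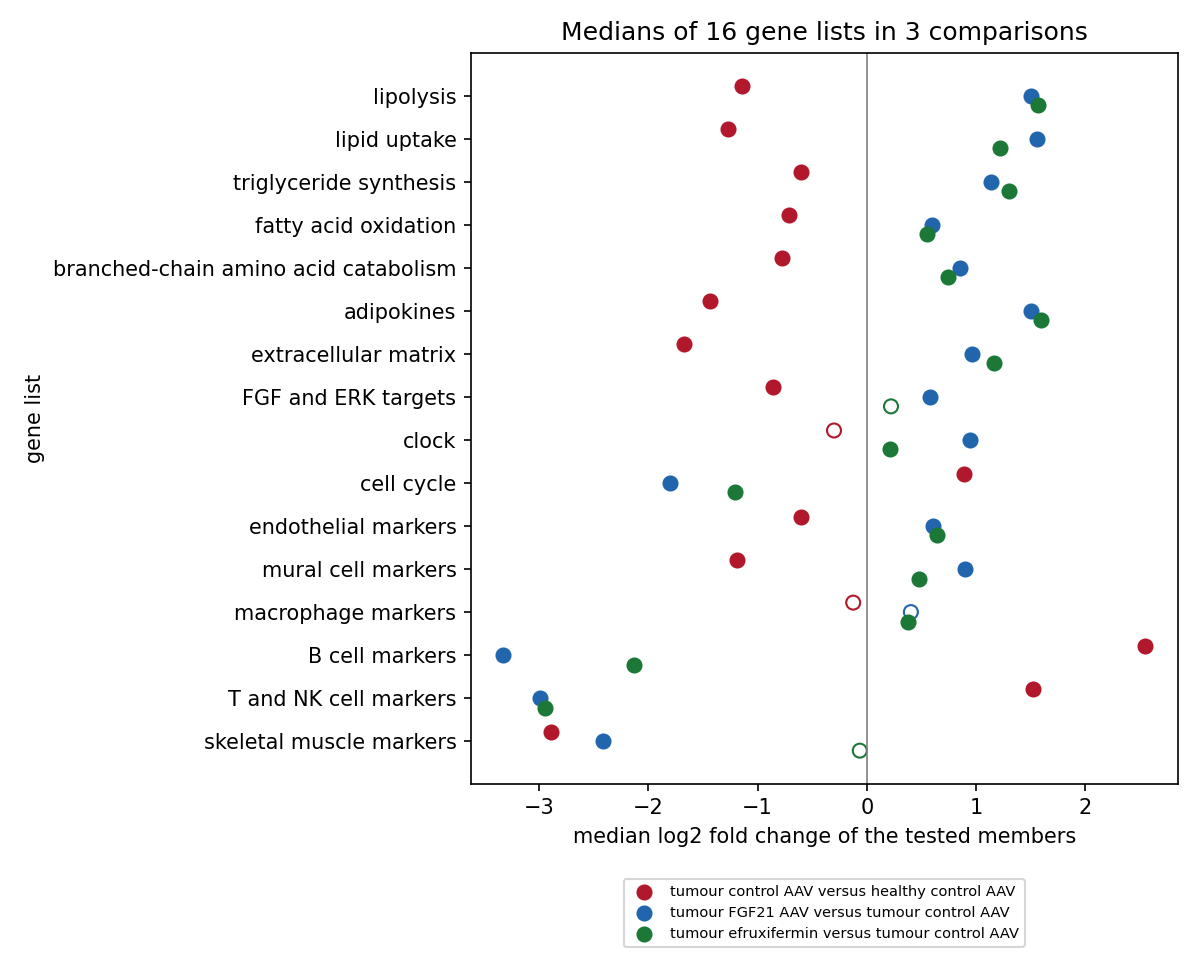
Median log2 fold change of the tested members of 16 gene lists in 3 comparisons, with filled points for lists called by camera with the preset correlation and open points for the others. Lipolysis stood at -1.14 in tumour controls against healthy mice and at 1.5 and 1.57 under the treatments against tumour controls.

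The treatments were compared with each other next. Of the genes called higher, 58 were shared by the 88 under FGF21 AAV and the 115 under efruxifermin, against 0.595 for independent lists, and the shared genes included Alb, Npr3, Pck1, Lpl, Rbp4, Aqp7 and Fgfr1. Of the genes called lower, 3 were shared by 8 and 15. Fold changes of the treatments correlated at 0.711 across 17013 genes, which are not independent replicates. Groups that share tumour controls give a correlation without any effect: simulated unchanged groups averaged 0.487, 9 of 100 simulations were as large, and with the tumour controls divided between the treatments the median over 20 divisions was 0.384 (0.111 to 0.456). Shared genes called higher numbered at most 8 in the simulations and 3 with divided controls. Those called lower numbered at most 3 in the simulations, as many as observed, and 0 with divided controls.

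Direct comparison of efruxifermin with FGF21 AAV called 0 genes by limma (945 at an unadjusted p under 0.05, smallest adjusted p 0.583), 0 by edgeR and 19 by DESeq2. Dbp had 33.2 ± 12.2 RPM under efruxifermin and 92.0 ± 16.7 RPM under FGF21 AAV (SD, n = 5 each, log2 -1.50 ± 0.37 SE, adjusted p = 0.7). The clock list was lower under efruxifermin, with 4 of 17 members down adjusted over the list alone (median -0.61, adjusted p = 0.00103, adjusted p = 0.821 with an estimated correlation). Fgfr1 differed by log2 -0.16 ± 0.32 (SE) and Lep by log2 -0.17 ± 0.59 (SE). In simulated libraries of these 2 groups, 0 of 67 genes changed 2-fold and 23 of 67 changed 4-fold were recovered. Muscle markers were higher (median 2.34, adjusted p = 0.00157, adjusted p = 0.991 with an estimated correlation), as were B cell markers (median 1.07, adjusted p = 0.00889, adjusted p = 0.991 with an estimated correlation), and 8 of 37 lists were called.

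**Figure D4:**
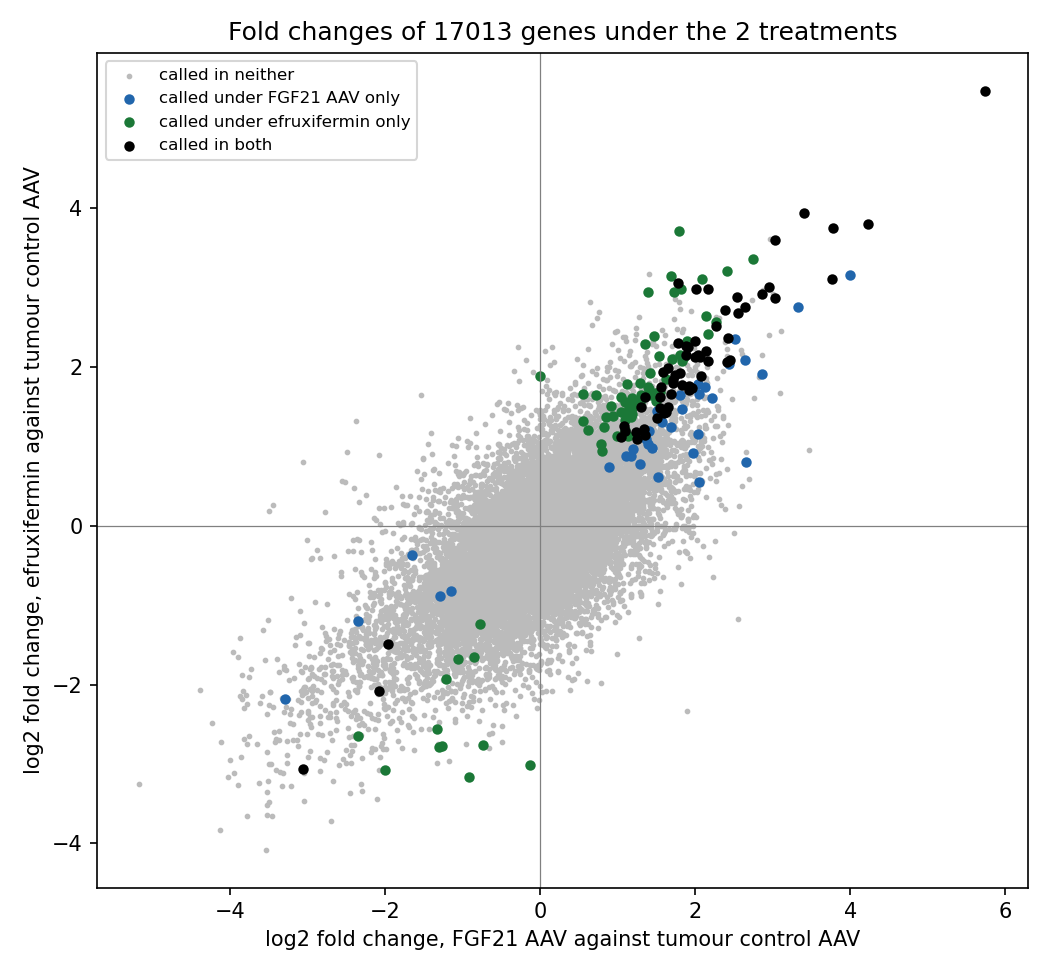
Log2 fold change of 17013 genes against tumour controls, FGF21 AAV on the horizontal axis and efruxifermin on the vertical axis, coloured by which comparison called the gene. The 58 genes called higher in both lie to the upper right and the 3 called lower in both to the lower left.

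Each treatment against healthy mice asks how far the treated depots stood from health. Under FGF21 AAV, Dbp was 8.72-fold higher (92.0 ± 16.7 RPM, SD, n = 5, against 10.8 ± 5.49 RPM, SD, n = 4) and Per3 4.14-fold higher, and these were the 2 called genes, with 908 at an unadjusted p under 0.05. The clock list was higher with 6 of 17 up and 1 down adjusted over the list alone (median 0.45, adjusted p = 5.78e-09, adjusted p = 0.0328 with an estimated correlation). Red blood cell markers were higher in 7 of 9 cases adjusted over the list alone (median 1.51, adjusted p = 9.4e-15, adjusted p = 0.0328 with an estimated correlation), with Alas2, the first enzyme of heme synthesis in red cells, at log2 2.27 ± 0.61 (SE, adjusted p = 0.569). Muscle markers were lower in 16 of 16 cases adjusted over the list alone (median -5.29, adjusted p = 7.2e-17, adjusted p = 0.2 with an estimated correlation). Extracellular matrix genes were lower than in healthy mice, 1 of 30 adjusted over the list alone (median -0.64, adjusted p = 0.00403, adjusted p = 0.623 with an estimated correlation), with Col6a3 at log2 -1.65 ± 0.42 (SE, adjusted p = 0.424). Progenitor markers (median -0.91, adjusted p = 0.00376, adjusted p = 0.264 with an estimated correlation) and cell cycle genes (median -0.89, adjusted p = 0.0071, adjusted p = 0.623 with an estimated correlation) were lower too. So were genes of creatine and calcium cycles (median -0.89, adjusted p = 0.00376, adjusted p = 0.218 with an estimated correlation) and nuclear genes of oxidative phosphorylation (median -0.35, adjusted p = 0.00273, adjusted p = 0.623 with an estimated correlation). In the creatine and calcium list Atp2a1 stood at 70.8 ± 120 RPM (SD, n = 5) against 1180 ± 1150 RPM (SD, n = 4). Ryr1 stood at 21.4 ± 29.1 RPM (SD, n = 5) against 209 ± 238 RPM (SD, n = 4). Muscle markers were lower in the same comparison, so the fall of this list cannot be told apart from a difference in muscle RNA. Over all genes the median was -0.223 in this comparison. Of 37 lists 19 were called, 13 higher and 6 lower. Without healthy 2, 3 or 4, or FGF21 AAV 2, 3, 4 or 5, the gene count was 1, it was 8 without FGF21 AAV 1, and 0 with the library number as a covariate or within the libraries with (2 against 2) or without (3 against 2) lymph node RNA.

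Under efruxifermin 0 genes differed from healthy mice by limma (1373 at an unadjusted p under 0.05, smallest adjusted p 0.272), 0 by edgeR and 17 by DESeq2. Lipolysis genes were higher as a list with 0 of 21 past the test adjusted over the list alone (median 0.33, adjusted p = 2e-04, adjusted p = 0.498 with an estimated correlation), and muscle markers lower with 4 of 16 (median -2.85, adjusted p = 3.71e-05, adjusted p = 0.498 with an estimated correlation). Genes of creatine and calcium cycles (median -1.12, adjusted p = 0.0359, adjusted p = 0.498 with an estimated correlation) and nuclear oxidative phosphorylation genes (median -0.35, adjusted p = 0.0359, adjusted p = 0.776 with an estimated correlation) were the other lists called lower. In the creatine and calcium list Ckmt2 had the smallest p (log2 -4.54 ± 1.17 SE, adjusted p = 0.334). As muscle markers were lower too, the fall of this list cannot be told apart from a difference in muscle RNA. Over all genes the median was -0.304 in this comparison, close to that of the oxidative phosphorylation list. Of 37 lists 15 were called, 12 higher and 3 lower. Lep stood at log2 0.77 ± 0.62 (SE, adjusted p = 0.755) and Dbp at 1.62 ± 0.40 (SE, adjusted p = 0.334). The count was 1 without efruxifermin 3.

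Reversal was measured on the genes called between tumour controls and healthy mice. Of the 8 genes lower in tumour controls, 8 had the opposite sign under FGF21 AAV and 8 under efruxifermin, and 5 were also called under each, with Alb, Npr3, Col5a3, Sncg and Slc5a3 called under both. Shared tumour controls favour opposite signs without any effect. Of the 1415 genes at an unadjusted p under 0.05, 94.5% and 89.8% had the opposite sign, against means of 85.9% (60.4% to 99.1%) and 86.9% (66.3% to 99.5%) in simulated unchanged groups. Dividing the controls removes the sharing and leaves any effect, and the median shares were then 77.9% (55.4% to 82.2%) and 70.3% (49.5% to 75.3%). No effect would give equal shares of both signs on average, but the spread around this was not simulated for divided controls. RNA of neighbouring tissues that the tumour controls have in common is not removed by the division either. The correlation of the tumour's and the treatment's fold changes across 17013 genes was -0.659 for FGF21 AAV and -0.615 for efruxifermin. Tumour controls enter both sides of it with opposite sign, and simulated unchanged groups gave -0.466 and -0.472, with 15 and 17 of 100 simulations as large. With the tumour controls divided between both sides, the medians were -0.302 (-0.437 to -0.0267) and -0.239 (-0.352 to 0.0343).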

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

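The tests of liver RNA, adipocyte loss, collection time, other fat cell types, and B cell and muscle scores as covariates were chosen after the result was seen. The deciding rules of all but the list tests with covariates were also made stricter after their values were known: liver RNA and collection time were first counted as favoured, and adipocyte loss, a smaller adipocyte share, and neighbouring tissue for the clock genes as argued against. Fgb, Cps1, Apob, Npas2, Clock and Nfil3 lie outside the rule for named genes and were chosen after values were seen.

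Of 76 groups of libraries checked for a library far from the others, 15 had one. For normally spread values chance alone gives about 1 in 20 groups, or 3.8 here. A group with reads in only 1 library is always flagged, so this figure does not hold for genes near 0 such as Fgf21 and Ucp1. In healthy mice, Lep was 17.9 RPM in replicate 1 (others 43.8 to 48.2). In replicate 4 Adipoq was 2192 RPM (others 714 to 851), Pnpla2 1260 RPM (others 411 to 527), and 15694 genes were detected (others 16820 to 17040). Among tumour controls, replicate 2 held Fgf21 at 0.757 RPM (others 0) and Dbp at 11.7 RPM (others 23.2 to 25.7). Tumour control 4 had a B cell score of 0.59 (others 6.84 to 8.13), Saa3 at 4.60 RPM (others 0 to 0.475) and Alb at 0.271 RPM (others 0). Under FGF21 AAV, replicate 5 held Ucp1 at 4.76 RPM (others 0) and replicate 2 Alb at 141 RPM (others 28.4 to 60.7). Under efruxifermin, replicate 1 held Ucp1 at 0.938 RPM and Saa3 at 14.7 RPM (others 0 for both), and replicate 3 had Lep at 10.2 RPM (others 86.7 to 115) and Npr3 at 18.9 RPM (others 85.9 to 101).

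The list test of the direct comparison of the 2 treatments called 8 lists. With 50 of 100 divisions of these libraries calling as many, a difference between the treatments' effects cannot be told from chance. Median log2 differences (efruxifermin minus FGF21 AAV) were 0.214 for unfolded protein genes, 0.282 for matrix genes, 0.556 for cell cycle genes, -0.607 for clock genes, 1.07 for B cell, 2.34 for skeletal muscle, -0.599 for mammary epithelial and -0.489 for red blood cell markers. With an estimated correlation 0 of these 8 passed.

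Lipid and adipokine lists were lower in tumour controls and higher under both treatments. With B cell and muscle scores as covariates 18 of 18 list tests were called in the same direction at the preset correlation. The 18 tests are not independent, since the comparisons share tumour controls. They cannot decide whether these neighbouring tissues were the whole cause, since other divisions of the libraries called as many lists at this correlation. Without covariates, 5, 22 and 18 of 100 divisions did so, the real one included, in tumour controls, FGF21 AAV and efruxifermin. In the same order gene counts were 13, 1 and 41 with the covariates, against 8, 96 and 130 without. None of these lists was called with an estimated correlation in the fit without covariates. Other scalings, first counted as argued against, could not decide, since the list test sets members against the other genes. A smaller share of adipocytes stays open: 0 of 5 lists of other fat cell types had a median above 0 in tumour controls, but the lower progenitor (-1.04), endothelial (-0.611) and mural (-1.07) medians gave adjusted p = 0.000103, 0.00825 and 0.000103 at the preset correlation and 0.153, 0.354 and 0.181 with an estimated correlation. A response of the tissue to the tumour and to FGF21 also stays open and was not tested.

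Liver-type transcripts had low means in tumour controls: 16 of 21 markers had their lowest mean there. They ran from Alb with 1 read to Fgb at 12.2 ± 8.5 RPM (SD, n = 5) against 25 ± 25.4 RPM (SD, n = 4) in healthy mice. Only 1 of the 16 tested markers, Alb, was called lower than in healthy mice. The markers were listed after the values were seen and had no list test. Over the 14 other libraries Alb and the other liver markers correlated at 0.793 (p = 0.00073, adjusted p = 0.00292), by rank at 0.688 (p = 0.00826, adjusted p = 0.0165), within groups at 0.753, and without FGF21 AAV 2 and efruxifermin 3 at 0.475 (p = 0.118). RNA from liver is a candidate explanation that cannot be told apart from expression in the fat, since markers expressed together in the fat would correlate too. Cps1 and Apob had 1 and 5 reads in these libraries, where Alb had 1899. Loss of adipocyte RNA stays open as well, since all 16 tested markers rose by a median of 2.59 (SD 1.22) under FGF21 AAV, within 1 SD of the adipokine median of 1.5.

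Clock genes were higher under FGF21 AAV. For Dbp the log2 change against tumour controls was 2.05 ± 0.374 (SE, adjusted p = 0.0227), higher in 5 of 5 libraries, and 2.41 ± 0.518 (SE, adjusted p = 0.234) with B cell and muscle scores as covariates. The call ended as the standard error grew while the change did not shrink, and 1 gene cannot decide for the group, so these tissues stay open. A different time of collection may shift the clock, which would move Arntl, Npas2, Clock and Nfil3 against the output genes; their median was -0.0281 (SD 0.744) beside 1.19 for the output genes. Collection time cannot be told apart from an effect of FGF21, since these 4 genes went both ways and the labels used here give no collection times.

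The same libraries were divided in other ways (100 divisions each). In FGF21 AAV against tumour control only the real division called as many genes (96, highest other 1, value 1). In FGF21 AAV against healthy few did (2, highest other 5, value 3), but another division called more genes than the real one. These values were not adjusted over the comparisons and do not cover differences tied to the groups, such as lymph node RNA. With B cell and muscle scores as covariates 1 gene was called in each of these 2 comparisons. Where 0 genes were called the value was fixed at 100, so the test could not decide. These were efruxifermin against FGF21 AAV (highest other 15) and efruxifermin against healthy (highest other 42). Chance cannot be excluded for the genes called in tumour control against healthy (8, highest other 958, value 5). Nor can it be excluded for efruxifermin against tumour control (130, highest other 1723, value 6). For lists it cannot be excluded in any of the 6 comparisons: 29 (highest other 30, value 5), 22 (28, value 22), 22 (28, value 18), 8 (20, value 50), 19 (21, value 6) and 15 (22, value 26), for tumour control against healthy, FGF21 AAV and efruxifermin against tumour control, efruxifermin against FGF21 AAV, and FGF21 AAV and efruxifermin against healthy. Each value is the number of divisions with as many calls, the real one included.

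The division with 958 genes set healthy 1, 3 and 4 with tumour control 4 (muscle score 9.52, 1 of 4 with lymph node RNA) against healthy 2 with tumour controls 1, 2, 3 and 5 (3.18, 5 of 5). The division with 1723 genes set tumour controls 1, 2, 3 and 5 with efruxifermin 5 (5 of 5 with lymph node RNA) against tumour control 4 with efruxifermin 1 to 4 (2 of 5), with muscle scores of 3.26 and 5.91. Each exchanged tumour control 4 with 1 library of the other group and kept the rest in place. Neither therefore shows how many genes would be called without any effect. Both point to a structure of the samples. What it follows was not settled: in FGF21 AAV against tumour control, the division with the most calls parted lymph node RNA as sharply (5 of 5 and 1 of 5) and called 1 gene.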

How the results depend on the processing

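Alternatives with B cell and muscle scores together, lymph node as a batch, libraries with or without lymph node RNA, without tumour control 4 and efruxifermin 3, without efruxifermin 2 and 3, and without Gm42418 were chosen after seeing the data. Of the values of single named genes, 2767 stayed on their side of the threshold, 805 lost it, 51 gained it and 113, of changes not called, turned sign; 0 called changes turned sign. Gene counts moved when single libraries were left out and in fits with B cell and muscle scores. Gm42418 lies outside the rule for named genes. At 2011067 to 3693864 reads, 0 to 5.97% of simulated 2-fold changes were recovered. Where not stated, the cause was not tested. The mark (fewer samples) below says only that a fit held fewer libraries. It is not given as a cause, and some counts rose in such fits.

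In the order tumour control against healthy (T), FGF21 AAV against tumour control (F), efruxifermin against tumour control (E), efruxifermin against FGF21 AAV (D), FGF21 AAV against healthy (FH) and efruxifermin against healthy (EH), gene counts were 8, 96, 130, 0, 2 and 0. Leaving out 1 library gave T 1 to 64, F 7 to 1015, E 4 to 599, D 0 to 2, FH 1 to 8 and EH 0 to 1; lists gave 19 to 26, 20 to 25, 19 to 27, 2 to 7, 15 to 24 and 8 to 19. Counts that moved over 1.5 times were: pseudocount 5, T 13, F 55. No filter, T 14, F 14, E 57, FH 6, EH 4. TMM, T 3, FH 4. Median-of-ratios, T 3. Quantile, T 5, F 198, FH 5. Without the 50 most abundant genes, T 5, F 255, FH 5. Robust moderation, T 23. Array weights, T 381, F 2342, E 639, FH 10. Others were: only 2 groups in the fit (fewer samples), T 1, F 60, E 1, FH 5; replicate block, T 40, F 150, FH 1. Library number, T 19, FH 0. B cell score, T 13, F 55, FH 15. With edgeR, T 1, F 8, E 46, FH 1. DESeq2, T 39, F 521, E 400, D 19, FH 28, EH 17. Chosen later were: B cell and muscle scores, T 13, F 1, E 41, FH 1. Libraries with lymph node RNA (fewer samples), T 0, F 1, E 298, FH 0. Without it (fewer samples), T 0, F 0, E 0, FH 0. Without tumour control 4 and efruxifermin 3, T 230, F 1760, E 732, FH 9, EH 8. Without efruxifermin 2 and 3, T 51, F 292, E 358. Without Gm42418, F 158.

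List counts that moved were: estimated correlation, 0, 0, 0, 0, 2 and 0. Fry, 9, 12, 0, 0, 0 and 0. Libraries without lymph node RNA, 11, 8, 8, 3, 12 and 7. B cell score, T 17, D 4. B cell and muscle scores, T 19. Quantile, D 5; lymph node as a batch (chosen later), D 5; library number, FH 12. The reversal correlation of FGF21 AAV was -0.526 with the B cell score, -0.414 with both scores and -0.496 in libraries with lymph node RNA, and that of efruxifermin -0.458 with both scores and -0.451 in those libraries. The agreement of the treatments was 0.615 with the B cell score, 0.565 with both scores, 0.610 in libraries with lymph node RNA, 0.5996 by edgeR and 0.550 by DESeq2.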

Other observations

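No test in this part was planned before the data were examined. Npas2, Clock and Nfil3 lie outside the rule for named genes. Against healthy mice, the median of Arntl, Npas2, Clock and Nfil3 was below 0 in all 3 tumour groups: -0.974 (SD 0.547) in tumour controls, -1.48 (SD 0.643) under FGF21 AAV and -1.46 (SD 0.657) under efruxifermin. The median of 7 output genes was 0.0807, 1.55 and 0.469 in the same order. These 3 comparisons share the healthy libraries, which favours a common sign without any effect. Efruxifermin against tumour controls gave 0.546 for the output genes and -0.287 for the other 4. Of the 21 liver markers listed, 16 were tested and 5 were called under either treatment. Alb and the adipokine list correlated at -0.224 (p = 0.441, adjusted p = 0.588) over the 14 libraries outside tumour controls.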
